A study of Mus musculus with 8 samples.

How the data were processed

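H3K27me3 ChIP-seq and RNA-seq were measured in naive CD4+ T cells of 4 genotypes, with 1 library per genotype and assay. Per the labels, alignment to mm9 used Bowtie 0.12.7, and only reads placed at a single location with at most 2 errors were used, and the submitters' processing notes also name bcl2fastq, Cufflinks and Cuffdiff without a role. The deposited ChIP values are a coverage signal: per the file headers, the area and the highest bin of a window around each transcription start site, which from the values are coverage per M reads summed over 25 bp bins of 6 kb windows, with each read extended to 151 bp. The deposited RNA values are a coverage signal too: per the file headers, the mean and the median over a gene's exons of the peak of coverage, which from the values are per M reads and not divided by length. The RNA files also give, per the file headers, another number, that of exons per gene. How the authors computed these columns, and whether input was subtracted, is not stated. Neither input nor spike-in was used here, so only relative differences between libraries can be read.

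The plan allowed for counts where they exist; the files hold signal, so values were used as deposited. The height of 1 read gives the depth per library: 79.7, 87.1, 78.2 and 88.2 M reads for ChIP and 36.1, 70.4, 40.7 and 94.1 M for RNA, in the order WT, Ezh1 KO, Ezh2 KO and double KO. A median ChIP window then holds 179, 204, 177 and 199 read equivalents. From these, counting intervals of 95% were computed for ChIP ratios (exact Clopper-Pearson). They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. None was computed for RNA, where a peak of coverage is no count.

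Each mutant was compared with WT, and the double KO with each single KO, as log2 ratios with a pseudocount of 1 for ChIP and 0.1 for RNA. A window or gene entered a comparison when its value was at least 1 in the higher library, and differences of at least 2-fold were counted. No p was computed, because no group has more than 1 library. Marked windows have a WT value of at least 4 times the median of background windows, and background windows are those of genes in the top WT RNA tertile, 7077 in number. Enrichment is the median of marked over the median of background windows within a library. Of the windows, 528 were at 0 in every library. In the RNA files 4403 genes have no symbol; these are counted but not named. The assays were joined by gene symbol, with 18484 symbols in both, and 1 gene had exon lists that differed between RNA files. Against the mm9 annotation, 74.6% of 17659 windows were centred on the annotated gene start.

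Before the data were examined, 31 gene lists were fixed. The median log2 ratio of each list was compared with 10000 random lists of the same size, each member drawn from the 101 features nearest in mean value, and a list is called outside when its percentile is under 2.5 or over 97.5. Members were drawn independently, so the percentile describes these libraries only. It measures neither variation between animals nor members of a list that move together, and the number of lists outside is no significance. Lists need at least 3 members over the minimum, which left 31 lists for ChIP and 19 or 20 for RNA. "Above" and "differed by" give the list median minus the median of its random lists. Overlaps between mutants were set beside independent lists and, for ChIP, beside 20 sets of simulated libraries that differ from WT by counting only. A peak of RNA coverage is no count, so the RNA simulations of this kind are not used.

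The rule for named genes was also fixed beforehand: Ezh1 and Ezh2, then for each mutant against WT up to 10 higher and 10 lower genes with the largest change among those at least 2-fold different and at 1 or more in the higher library, then from each list the 4 members with the largest change in the double KO and any member at least 2-fold different in a single KO. In both assays the order was by the log2 ratio itself, as planned for values that are not counts. Genes of near-identical families are named only as uncertain.

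The calls were tested on simulated data, in which RNA coverage was treated as counts. In libraries simulated from the WT values, 200 features per assay were changed, all drawn from those at 2 or more in WT. All of those changed 3-fold or 4-fold upward were recovered, 48 of 50 ChIP windows and 50 of 50 RNA genes were recovered at a factor of 0.33, and 0 unchanged features passed 2-fold. Recovery of changes in features under 2 in WT, where many of the named RNA differences lie, was not tested. The simulated libraries hold counting error only, so this says nothing about false calls from variation between animals or preparations.

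Alternatives tried were other scalings (TMM, trimming 30% of ratios and 5% of levels, median of ratios, background scaling), pseudocounts, minimum values, size thresholds of 1.5-fold and 4-fold, other definitions of marked and background windows, the mean of a list, and RNA without ribosomal, receptor, mitochondrial and sex-linked genes. Added after seeing the data were the highest bin of the window, scaling on marked promoters, the median over exons, and random lists matched on WT RNA. For the highest bin, the ChIP pseudocount and minimum were divided by 6.04, the value of 1 read over its height. Highest bins in WT were 0.143 to 0.423 at the other windows within 50 kb of Cd4. That pseudocount is large beside them, so highest-bin ratios shrink and fewer pass 2-fold by construction. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. TMM and median of ratios were written in Python.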

Results

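H3K27me3, the histone mark placed by the Polycomb complex PRC2, and RNA were measured in naive CD4+ T cells purified from lymph nodes of 129SV/B6 mice. Ezh1 and Ezh2 are the alternative catalytic subunits of PRC2. Cells came from 4 genotypes, named here as the labels give them: WT, Ezh1 -/- (Ezh1 KO), Ezh2 fl/fl with CD4-cre (Ezh2 KO, in which a cre recombinase driven by Cd4 regulatory sequence removes a floxed part of Ezh2 during T cell development), and both together (double KO). Each genotype has 1 H3K27me3 ChIP-seq library and 1 RNA-seq library, 8 libraries in all. There are no replicates, so no difference between libraries has an SD, a p or a test, and "higher" and "lower" describe single libraries. The depth implied by the height of 1 read in the ChIP files was 79.7 M reads in WT, 87.1 in the Ezh1 KO, 78.2 in the Ezh2 KO and 88.2 in the double KO. In the RNA files it was 36.1 M reads in WT, 70.4 in the Ezh1 KO, 40.7 in the Ezh2 KO and 94.1 in the double KO. H3K27me3 is given as summed coverage per M reads in 18603 promoter windows of 6 kb, and RNA as the mean over exons of peak coverage per M reads in 22410 genes. The comparisons ask what each PRC2 enzyme contributes to H3K27me3 and RNA in these cells.

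Ezh1 RNA was 1.05 in WT and 1.12 in the Ezh2 KO, against 0.196 in the Ezh1 KO and 0.194 in the double KO. Over the median of its 21 exons it was 0.960 in WT and 0.0335 in the Ezh1 KO. Ezh2 RNA was 0.925 in WT, 0.913 in the Ezh1 KO, 1.08 in the Ezh2 KO and 1.17 in the double KO, and over the median of its exons 0.753, 0.685, 0.737 and 1.04. A deletion of a few exons need not show in a mean over 21 exons, so these Ezh2 values do not check the Ezh2 deletion, which rests on the labels. Among the other PRC2 subunits, Eed RNA was 3.93 in WT and 3.10 in the double KO, and Rbbp4 RNA was 5.30 and 4.37. H3K27me3 at the Ezh1 promoter was 17.2 in WT and 17.0 in the double KO, and at the Ezh2 promoter 12.5 and 10.2.

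H3K27me3 at Polycomb target promoters was present in all 4 genotypes, the double KO included. Since the Ezh2 deletion could not be checked from RNA, this does not show that the mark persists without both enzymes. At the 30 Hox promoters with signal, which encode body-axis transcription factors, the median was 68.6 in WT, 87.1 in the Ezh1 KO, 72.6 in the Ezh2 KO and 83.2 in the double KO. The other 9 of the 39 Hox windows were listed at 0 in every library. Over the 88 windows with signal among 94 non-lymphoid developmental transcription factors, the others again listed at 0, the median was 54.6 in WT, 75.0 in the Ezh1 KO, 54.9 in the Ezh2 KO and 70.9 in the double KO. In WT, 81 of these 94 windows and 26 of the 39 Hox windows were marked, meaning at least 4 times the background median. Background windows are those of the 7077 genes with the highest WT RNA. Across 2231 marked windows, 12.0% of all windows, the median was 5.08 times background in WT, 6.54 in the Ezh1 KO, 4.29 in the Ezh2 KO and 5.47 in the double KO. Relative to WT these enrichments were 1.29, 0.844 and 1.08, with no spike-in to set an absolute scale. In the order WT, Ezh1 KO, Ezh2 KO and double KO, marked medians were 51.5, 64.2, 47.5 and 56.9. Background medians were 10.1, 9.82, 11.1 and 10.4. With 1 library per genotype, differences over marked promoters cannot be told apart from differences in ChIP efficiency between libraries. Marked genes were mostly silent: their median WT RNA was 0.00997, and 44 of them (1.97%) reached 1, against a median of 0.142 and 26.3% reaching 1 across all windows, the marked ones included.

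**Figure D1:**
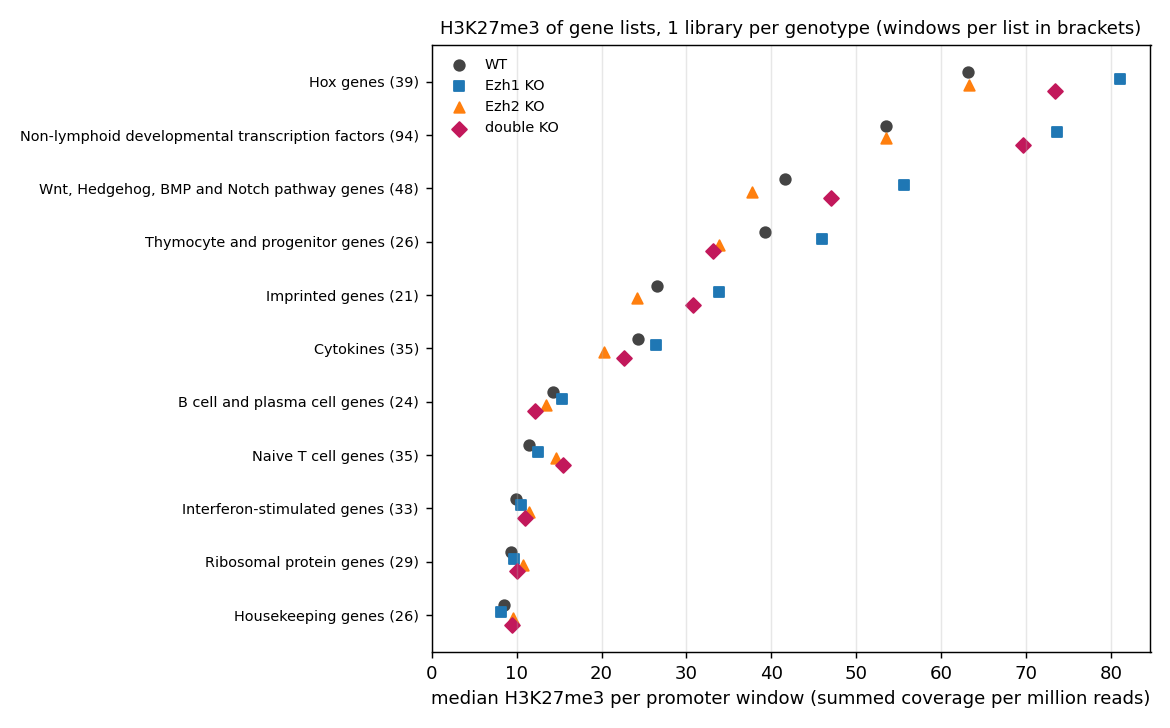
Median H3K27me3 per promoter window (x axis, summed coverage per M reads) of 11 gene lists (y axis, windows per list in brackets), with 1 point per genotype and 1 library behind each point. Hox windows have medians of 63.1 in WT and 73.3 in the double KO when windows at 0 are included, and housekeeping windows 8.55 and 9.49.

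In the Ezh1 KO, H3K27me3 was higher than in WT over most marked promoters, with a median log2 ratio of 0.29 across the 2231 windows and 5th and 95th percentiles of -0.03 and 0.57. Single windows rarely differed by 2-fold: 2 were higher and 4 lower. The higher pair were Bcl11b, a transcription factor of T cell commitment, at 14.5 in WT and 30.7 in the Ezh1 KO (log2 ratio 1.04, counting interval 0.84 to 1.34), and Sall1, a developmental zinc finger factor, at 30.5 and 62.1. Among the lower windows, Coil on chromosome 11 (mm9, 88828566 to 88834566) went from 132.8 in WT to 17.7, and 2310001H12Rik from 5.55 to 2.01. The developmental transcription factors had a median log2 ratio of 0.42, which was 0.10 above level-matched random lists. Wnt, Hedgehog, BMP and Notch pathway genes had a median of 0.45, which was 0.16 above them. With random lists matched on WT RNA, the excess was 0.20 for the developmental factors and 0.27 for the pathway list. The developmental factors and this pathway list were the 2 of 31 lists outside the middle 95% of random lists, where independent draws give 1.55. No member of either list reached 2-fold. Independent draws leave out variation between animals and members that move together. The other 29 lists lay between -0.14 and 0.09 of their random lists. The 2-fold split depends on scaling: it was 0 higher and 4 lower with TMM or median of ratios, 3 and 3 with background scaling, 0 and 7 when marked promoters were set equal, 1 and 1 in the highest bin of each window, and 0 and 1 with a pseudocount of 10. In this and later comparisons the pseudocount is large beside the highest-bin values, which lowers those counts by construction.

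In the Ezh2 KO, marked promoters were slightly lower than in WT, with a median log2 ratio of -0.12 and percentiles of -0.37 and 0.12, while promoters of naive T cell genes were higher. The largest difference was at Cd4, the co-receptor gene, with 19.9 in WT, 24.1 in the Ezh1 KO and 193.5 in the Ezh2 KO (log2 ratio 3.22, counting interval 3.10 to 3.47). The window lies on chromosome 6 (mm9, 124835239 to 124841239), and the CD4-cre transgene itself carries Cd4 regulatory sequence. The naive T cell list, with 30 of 34 windows higher, was 0.35 above matched random lists, and 0.18 above when these were matched on WT RNA. Hox genes were 0.09 above them and the developmental factors 0.06 above, and neither list lay outside when its mean was used. B cell and plasma cell genes differed by -0.17 from theirs and myeloid and dendritic cell genes by -0.09. In the RNA library of the same genotype the B cell list was 0.93 above its random lists. In all, 5 of 31 lists lay outside, where independent draws give 1.55, and the other 26 lay between -0.18 and 0.10. Only 3 windows were at least 2-fold higher and 3 lower, among them Trim5, Klrc2 and Klra10, which belong to near-identical families and are uncertain. With background scaling the split was 1 higher and 12 lower, with marked promoters set equal 6 and 2, and 1 and 0 in the highest bin or with a pseudocount of 10.

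In the double KO, most marked promoters had a signal near that of WT, with a median log2 ratio of 0.12 and percentiles of -0.28 and 0.41, and a small set of windows was lower. Of the 25 windows at least 2-fold lower, 6 were marked in WT: Coil, BC013712, Atp6v0a4, Lamc1, Hes1 and Atf6, the last outside the naming rule and chosen after its value was seen. Atp6v0a4, a proton pump subunit, went from 57.7 to 22.7, Lamc1, a laminin chain, from 45.3 to 20.4, and Hes1, a Notch target, from 43.2 to 21.1. BC013712 went from 42.2 to 15.5 (log2 ratio -1.39, counting interval -1.68 to -1.22). Cbfa2t3 went from 20.2 to 7.87, Pik3ap1 from 34.6 to 14.4, Gab2 from 39.5 to 16.6, Irf5 from 25.4 to 11.1 and Bhlhe40 from 22.0 to 10.5. Sgk3 went from 34.8 to 15.1 and Plekhg3 from 33.2 to 14.8. The 6 windows at least 2-fold higher were Cd4 at 212.1, Bcl11b at 34.7, Tnfrsf1a (22.5 in WT, 50.3 in the double KO), Socs3 (8.77 and 19.8), BC021614 (17.0 and 36.4) and the uncertain Trim12. With marked promoters set equal 3 windows were higher and 50 lower, in the highest bin 1 and 2, and 1 and 3 with a pseudocount of 10.

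**Figure D2:**
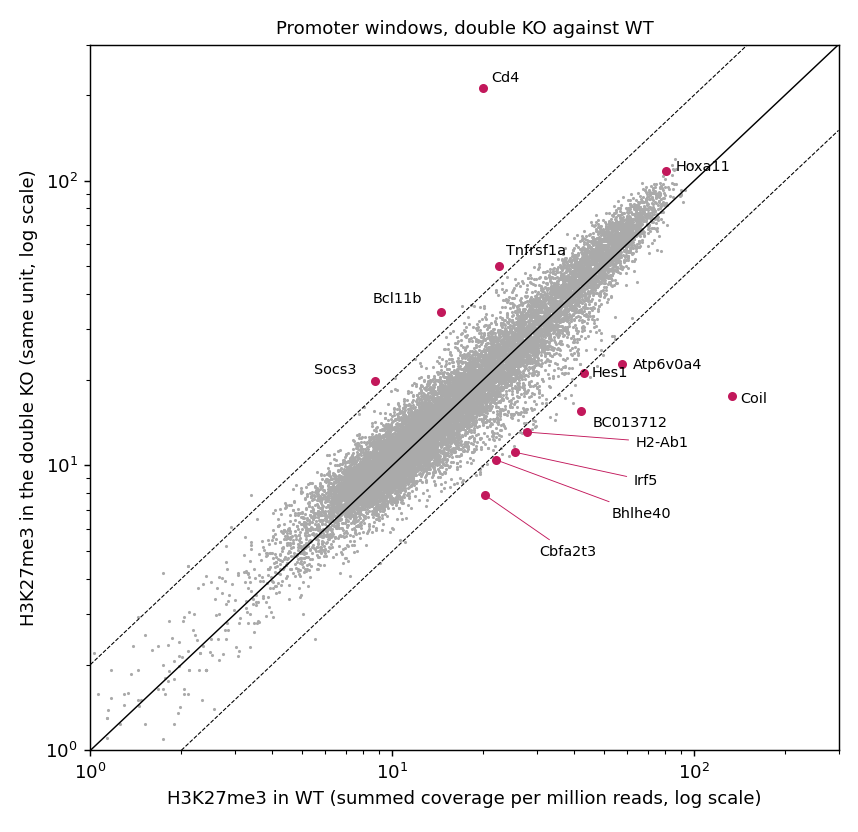
H3K27me3 per promoter window (summed coverage per M reads, log axes) in WT (x) and the double KO (y), 1 library each, for windows at 1 or more in both, with dashed lines at 2-fold. Cd4 (19.9 in WT, 212.1 in the double KO) lies far above and Coil (132.8, 17.5) far below the line of equal values.

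Among the fixed lists, H3K27me3 in the double KO was higher at naive T cell genes and lower at B cell genes than at windows of like level. In the naive T cell list 29 of 34 windows were higher than in WT and 2 by at least 2-fold, and its median log2 ratio of 0.40 was 0.35 above random lists. Tcf7, a transcription factor of naive T cells, was at 18.6 in WT and 36.4 in the double KO, and Actn1 at 25.2 and 41.9. In the B cell and plasma cell list, 1 of 24 windows was at least 2-fold lower and the median was -0.27, which differed by -0.30 from random lists. Its class II gene H2-Ab1 was at 28.0 and 13.1, the complement receptor gene Cr2 at 31.2 and 17.7, and Btk at 12.9 and 7.20. The RNA of this B cell list was 1.79 above its random lists in the same genotype. The developmental factors were 0.18 above, with Sox3 at 16.8 and 29.0 and Otx1 at 45.5 and 71.8. The Wnt, Hedgehog, BMP and Notch pathway list was 0.12 above, with Gdf6 at 60.1 and 85.5. Th2 genes were 0.18 above, although Il9 went from 54.5 to 27.8, Treg genes 0.15, and chemokine receptor and adhesion genes 0.11. Ribosomal protein genes were 0.09 above, but within the random range with TMM, background scaling, the mean, or lists matched on WT RNA, and the 4 measured sex-linked windows differed by -0.29. With the mean in place of the median, the Th2 and the chemokine receptor lists lay within the random range. Of 31 lists 9 lay outside, where independent draws give 1.55, and the other 22 lay between -0.09 and 0.09.

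Against the Ezh1 KO, the double KO was lower over marked promoters, with a median log2 ratio of -0.17, and had 3 windows at least 2-fold higher and 37 lower. B cell genes differed by -0.40 from matched random lists, while naive T cell genes were 0.32 above them, Tfh genes 0.30, Treg genes 0.13, housekeeping genes 0.11 and the developmental factors 0.06. Against the Ezh2 KO, the double KO was higher over marked promoters, with a median of 0.23, and had 3 windows higher and 3 lower. Imprinted genes were 0.18 above random lists in that comparison, the developmental factors 0.16 and the Wnt, Hedgehog, BMP and Notch pathway list 0.10. B cell genes differed by -0.14, thymocyte and progenitor genes by -0.10 and cell cycle genes by -0.08. In each comparison 6 of 31 lists lay outside. When marked promoters were set equal, the split against the Ezh1 KO was 5 higher and 9 lower, and against the Ezh2 KO 1 and 10. Against the Ezh1 KO it was 3 and 22 with median of ratios, 3 and 23 with TMM, 3 and 54 with background scaling and 1 and 3 with a pseudocount of 10. The highest bin gave 1 and 0 against the Ezh1 KO and 0 and 1 against the Ezh2 KO. TMM or median of ratios gave 1 and 3 against the Ezh2 KO, background scaling 4 and 2, and a pseudocount of 10 gave 0 and 1. Matched on WT RNA, the Treg, housekeeping, and thymocyte and progenitor lists lay within the random range, and the cell cycle list did so with the mean. The naive T cell list against the Ezh1 KO was 0.15 above random lists matched on WT RNA.

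In RNA, the Ezh1 KO differed little from WT outside Ezh1 itself: of 5201 genes 8 were at least 2-fold higher and 15 lower. Cox5b, a respiratory chain subunit, went from 16.3 to 5.47, 2310036O22Rik from 10.1 to 3.45, 2810432D09Rik from 1.92 to 0.675, the Mediator subunit gene Med9 from 1.39 to 0.581, and the interferon-inducible Ifi204 from 1.39 to 0.566. Ccdc107 went from 25.6 to 52.3. Amy2a2, Amy2a3, Amy2a4 and Amy2a5, near-identical pancreatic amylase genes, were at 0.114 to 0.119 in WT and 1.86 to 1.89 in the Ezh1 KO, and with the histone gene Hist1h2bb they are uncertain. Interferon-stimulated genes had a median log2 ratio of 0.22 over 26 members, 0.36 above matched random lists, and only Ifi204 among them reached 2-fold, downward. Of the list, 22 genes were at 1 or more in WT, and the rest of the 26 passed through the Ezh1 KO value alone. In all 4 of 19 lists lay outside, where independent draws give 0.95. The other lists were B cell and plasma cell genes at 0.48 above with 5 members (0.21 without a minimum), cell cycle genes at 0.14 and histone modifiers at 0.12. The median of all genes was -0.13 in the Ezh1 KO, -0.04 in the Ezh2 KO and -0.10 in the double KO, so list values are given relative to random lists. Summed RNA values were lower in the deeper Ezh1 KO and double KO libraries (34606 and 35081) than in WT and the Ezh2 KO (38565 and 38292). Whether depth shifts a peak of coverage was not tested, so small RNA ratios cannot be told apart from such a shift. With TMM the split was 13 higher and 13 lower, with median of ratios 13 and 14, and 8 and 3 with a pseudocount of 1. The histone modifier list lay within the random range with the mean and the cell cycle list without a minimum. The differences at Ccdc107, Cox5b, Ifi204 and 2310036O22Rik fell under 2-fold with the median over exons.

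In the Ezh2 KO, interferon-stimulated RNA was higher than in WT: 11 of 30 members were at least 2-fold higher and none lower, and the list was 0.87 above matched random lists. Of the list, 22 genes were at 1 or more in WT. The rest of the 30, Oasl2 and Ifi44 among them, passed the minimum through the Ezh2 KO value alone. The antiviral gene Oasl2 was at 0.677 in WT and 4.77 in the Ezh2 KO, Ifi44 at 0.314 and 2.29, the ubiquitin-like modifier Isg15 at 3.94 and 13.8, Ifit3 at 11.5 and 32.9, and the transcription factor Irf7 at 3.85 and 9.69. Gzma, a granule protease, was at 0.226 and 2.90, Plac8 at 0.680 and 7.47, the NK receptor gene Klrb1c at 0.110 and 1.03, and Ccl5 at 0.918 and 2.08. Of the CD8 T and NK cell list 5 members passed the minimum, and 3 of these, Gzma, Klrb1c and Ccl5, were under 1 in WT and passed through the Ezh2 KO value alone. The list was 1.15 above random lists with those 5 members and 0.34 above without a minimum. Prf1 went from 1.43 to 1.07 and Cd8b1 from 1.02 to 0.975. NKT and innate-like T cell genes lay within the random range, at 0.14. B cell and plasma cell genes were 0.93 above with 7 members and 0.58 above without a minimum. Of the 7, Igj, the antibody joining chain, went from 0.260 to 1.79, H2-Aa from 0.771 to 1.64 and Fcer2a from 0.668 to 1.09, and these 3 passed through the Ezh2 KO value alone. Cell cycle genes were 0.40 above, with Birc5 at 0.640 and 1.59 and Tyms at 4.14 and 6.66, and Tfh genes 0.29 above.

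Lower RNA in the Ezh2 KO included naive T cell genes, which differed by -0.17 from random lists without any member at 2-fold. S1pr1, which lets T cells leave lymph nodes, was at 20.4 in WT and 12.9 in the Ezh2 KO, and Dapl1 at 17.9 and 10.4. The calcium-binding genes S100a4 and S100a6 were at 3.71 and 1.16, and at 2.83 and 1.02. Zfp36l2, an RNA-binding protein gene, was at 13.0 and 6.05, Purb at 15.2 and 6.93, Adpgk at 1.74 and 0.781, and Cox5b at 16.3 and 6.01. Id2 was at 3.65 and 7.41, Ccr9 at 0.632 and 1.54, the CDK inhibitor gene Cdkn2c at 0.426 and 1.04, and Mid1 at 0.145 and 1.24. In all 59 of 5347 genes were at least 2-fold higher and 21 lower. Of 20 lists 6 lay outside, where independent draws give 1.00, and the other 14 lay between -0.09 and 0.14. The median over exons gave 59 higher and 37 lower, a pseudocount of 1 gave 27 and 9, and a minimum of 5 gave 19 and 8. The Tfh list lay within the random range with the mean.

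In the double KO, B cell and interferon-stimulated RNA were higher than in WT, and 57 of 5313 genes were at least 2-fold higher against 9 lower. In the B cell and plasma cell list 10 of 11 members over the minimum were at least 2-fold higher, and the list was 1.79 above matched random lists, and 1.28 without a minimum. Only 4 of the 11 were at 1 or more in WT. Cd74, the class II invariant chain, was at 1.51 in WT and 5.30 in the double KO, H2-Ab1 at 2.45 and 8.37, H2-DMb2 at 0.248 and 1.28, and Bank1 at 0.315 and 1.29. Among interferon-stimulated genes 13 of 30 were at least 2-fold higher, and the list was 0.93 above. Of this list, 22 genes were at 1 or more in WT. The rest of the 30, among them Ifi44, Oasl2, Oasl1 and Rsad2, passed through the double KO value alone. Ifi204 was at 1.39 and 0.555, a direction that turned with the median over exons (log2 ratio 0.15). Ifi44 was at 3.14, Oasl2 at 3.00, Oasl1 at 1.18 (0.256 in WT), Rsad2 at 2.07 (0.593 in WT) and Isg15 at 10.9, and 11 members reached 2-fold in the Ezh2 KO as well. Gzma was at 1.14 and Plac8 at 3.04. The CD8 T and NK cell list was 1.17 above with 4 members, of which Gzma and Ccl5 were under 1 in WT and passed through the double KO value alone, and without a minimum it was within the random range, at 0.02. Ifitm3 was at 0.350 and 1.57, Glycam1 at 0.244 and 1.47, Lyz2 at 0.275 and 1.19, and Psp was listed at 0 in WT and at 1.55 in the double KO. Cell cycle genes were 0.26 above and histone modifiers 0.19. The uncertain Slfn9 belongs to a near-identical family.

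Lower in the double KO were Gbp1, an interferon-inducible GTPase gene, at 1.11 in WT and 0.0245, Dapl1 at 17.9 and 4.06, and 2210010C17Rik at 2.59 and 0.705. Xlr3b, of a near-identical family and uncertain, was at 1.05 and 0.290. Naive T cell genes as a list were 0.02 from their random lists, with S1pr1 at 20.4 and 13.1 and Tcf7 at 10.1 and 13.8. Of 19 lists 5 lay outside, where independent draws give 0.95, and the other 14 lay between -0.15 and 0.14. With a pseudocount of 1 the 2-fold split was 22 higher and 4 lower, and with a minimum of 5 it was 15 and 2. The histone modifiers lay within the random range with the mean.

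**Figure D3:**
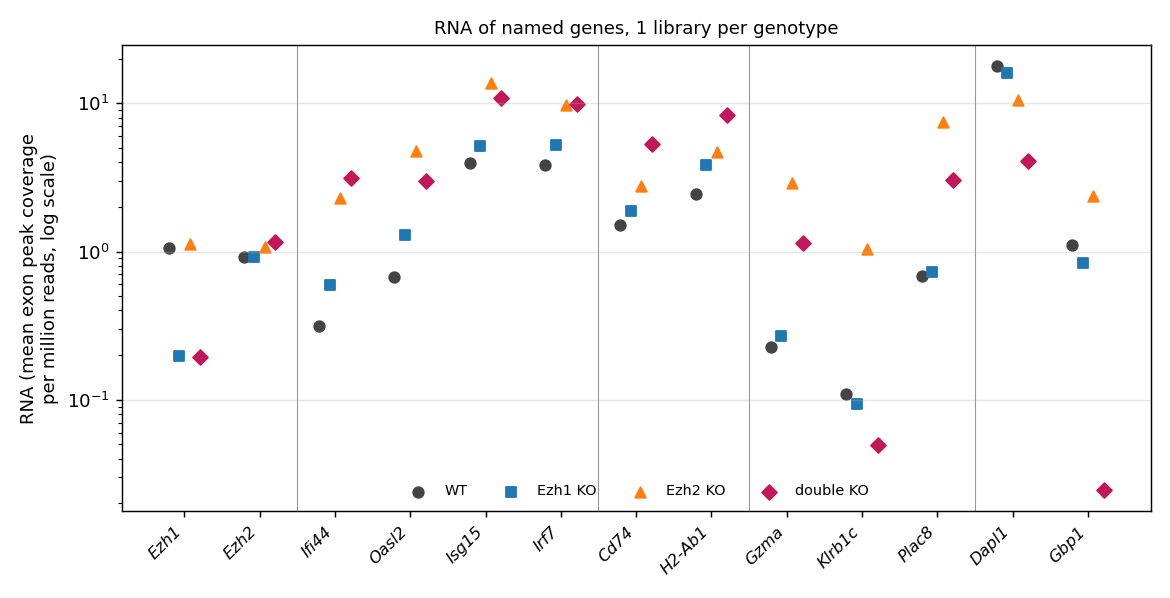
RNA (y axis, mean exon peak coverage per M reads, log scale) of 13 named genes (x axis) with 1 point per genotype and 1 library behind each point. Ifi44 lies at 0.314 in WT and 3.14 in the double KO, and Dapl1 at 17.9 and 4.06.

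Against the Ezh1 KO, 37 of 5096 genes had at least 2-fold higher RNA in the double KO and 8 lower, a split that was 3 and 6 with a pseudocount of 1, 7 and 1 with a minimum of 5, and 88 and 27 without a minimum. B cell genes were 1.11 above random lists, with 10 of 11 members at 2-fold, CD8 T and NK cell genes 0.82, interferon-stimulated genes 0.60 with 9 of 30 at 2-fold, and cell cycle genes and stress genes 0.11 each. Treg genes differed by -0.42 and Th1 genes by -0.21. Against the Ezh2 KO, 18 of 5218 genes were higher and 23 lower. B cell genes were 0.79 above, stress genes 0.43, naive T cell genes 0.23 and histone modifiers 0.17, and Tfh genes differed by -0.44 and cell cycle genes by -0.21. Interferon-stimulated genes were within the random range there, at 0.05. Median of ratios gave 28 higher and 16 lower against the Ezh2 KO and the median over exons 30 and 20, while a pseudocount of 1 gave 2 and 8, a minimum of 5 gave 2 and 5 and no minimum 45 and 91. Against the Ezh1 KO the CD8 T and NK cell list reversed to -0.0035 without a minimum and the stress list to -0.0142 with the mean, and the Treg and Th1 lists lay within the random range with the mean, as the Tfh and histone modifier lists did against the Ezh2 KO. With TMM the Th1 list and the histone modifier list also came within it.

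The few genes whose promoters had at least 2-fold less H3K27me3 in the double KO had a higher median RNA ratio than genes of like expression. B cell and plasma cell genes moved the same ways in these libraries, with RNA 1.79 above and H3K27me3 -0.30 from their random lists. Over the 6 marked promoters at least 2-fold lower the median RNA log2 ratio was 0.23, at the 98.2 percentile of matched random lists, against 0.00 for the 2223 marked genes that were not lower and -0.03 for 16255 unmarked genes. With marked promoters taken at 2 times background, 24 were lower and their median was 0.45, at the 100 percentile. Across all 25 lower windows the median was 0.44, with 21 of 25 genes higher and 4 by at least 2-fold, the B cell list member H2-Ab1 among them, but only 3 of the 25 reached an RNA of 1 in any library. At such low RNA, a small share of other cells in the double KO RNA library was not separated from a change in the T cells. The higher RNA thus cannot be read as a result of the lower H3K27me3. No marked promoter was 2-fold lower in the Ezh2 KO, and 1 was in the Ezh1 KO.

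Overlap between mutants was largest for higher RNA. Of genes with a ratio in both, 45 were at least 2-fold higher in the Ezh2 KO and 43 in the double KO, and 30 in both, interferon-stimulated genes among them, where independent lists would share 0.370. The Ezh1 KO and Ezh2 KO shared 6 higher genes, 4 of them the near-identical and uncertain Amy2a2 to Amy2a5, and 9 lower genes, and the Ezh1 KO and double KO 3 and 3. Each pair shares its WT library. The covariance of RNA log2 ratios was 0.0688 for the Ezh2 KO and double KO, 0.0566 for the single KOs and 0.0443 for the Ezh1 KO and double KO. A peak of coverage is no count, so these RNA values have no counting error to be set beside. For H3K27me3 the covariance was 0.0320 for the Ezh2 KO and double KO, 0.0292 for the Ezh1 KO and double KO and 0.000895 for the single KOs, against 0.0101, 0.0101 and 0.0102 in simulated libraries that differ only by counting. The single KOs thus lay below the simulated H3K27me3 covariance, and 46.6% of their windows had the same sign, against 67.0% simulated. Their median log2 ratios moved apart with WT level. Under background they were -0.0031 in the Ezh1 KO and 0.17 in the Ezh2 KO, and at 4 to 6 times background 0.30 and -0.13. Differing ChIP efficiency of single libraries was not separated from genotype in this. For the other pairs and for RNA, how much of the covariance comes from variation of the shared WT library beyond counting cannot be split from these libraries. No pair shared more than 1 window in either direction at 2-fold.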

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

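All tests in this part were chosen after the results they weigh had been seen. The effect of the Ezh2 genotype (fl/fl with CD4-cre) on cells with Ezh1 (Ezh2 KO over WT) and on cells without it (double KO over Ezh1 KO) was compared at 17662 ChIP windows and 5103 RNA genes, and features that went at least 2-fold in opposite directions are listed; there were 0 windows and 6 genes. Gbp1 RNA had log2 ratios of 1.04 and -2.91, a difference of 3.94, and 2310036O22Rik RNA had -1.34 and 1.09, a difference of -2.44. The 4 near-identical amylase genes, which are uncertain, differed by 6.46 (Amy2a2), 6.50 (Amy2a3), 6.49 (Amy2a4) and 6.48 (Amy2a5). With 1 library per genotype the difference was not tested. Coil lies 12.3 Mb from Ezh1 on chromosome 11. Its H3K27me3 was 132.8 in WT and 110.0 in the Ezh2 KO, against 17.7 and 17.5 in the Ezh1 KO and double KO. The mice are of mixed strain background, so DNA linked to the Ezh1 allele cannot be told apart from loss of Ezh1 at Coil. Strain variants that differ between animals likewise cannot be told apart from genotype at Coil or Gbp1.

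The Cd4 window had more H3K27me3 in both libraries with CD4-cre, at 193.5 and 212.1 against 19.9 in WT. A gain across the region is argued against by the other 6 windows within 50 kb, whose median log2 ratio in the double KO was 0.20 with a range of 0.04 to 0.76. Extra copies of Cd4 regulatory sequence in the transgene may account for the ratio, which was at least 3.22 in the libraries with CD4-cre, and so may a gain at the Cd4 promoter alone, with Cd4 RNA in the double KO at a log2 ratio of -0.0261. These cannot be told apart because the cre and the floxed Ezh2 always go together.

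In the double KO 25 windows had at least 2-fold less H3K27me3 than in WT. Chance high values in the WT library as the sole source are argued against by the Ezh2 KO over the Ezh1 KO, which uses neither library that chose the windows. Its median log2 ratio was -0.62, against -0.32 in level-matched lists. Of the 25 windows 24 were negative, but the share in matched windows, themselves mostly negative by their median, was not computed. Without WT in it, this ratio cannot show how much a high WT value added. Windows of like level were not lower in general, with matched lists at 0.0329, so a loss shared by such windows is argued against. The median of -1.07 at the 25 windows follows from how they were chosen. Values per M reads without a spike-in cannot show a library-wide loss, so ChIP efficiency as such was not tested. Cells of another type at a like share in both double KO libraries would have to make up a large part of each, which the naive T cell RNA list, at 0.0209 from its random lists, argues against. Other cells in the ChIP library alone cannot be told apart from a change in the T cells. Naive T cell windows had more H3K27me3 than matched lists (excess 0.35) and B cell windows less (-0.30), as either might give. The labels do not say whether both assays used the same cells. Over WT, the median log2 ratio at the 25 windows was -0.61 in the Ezh2 KO and -0.00 in the Ezh1 KO, but the WT library helped to choose them. Local dependence on Ezh2, or on both enzymes, remains an untested hypothesis.

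Interferon-stimulated RNA was higher in both libraries from Ezh2 fl/fl CD4-cre cells, in which the Ezh2 deletion itself could not be checked from RNA. Loss of H3K27me3 at these promoters is argued against by a median log2 ratio of 0.14 in the double KO, and none of the 33 windows was marked in WT. B cells as the source are argued against by the double KO over the Ezh2 KO, in which the B cell list was 0.79 above random lists and the interferon list 0.046. Exposure of single animals may account for it and cannot be told apart from an effect of genotype, because there is 1 library per genotype and the list was also 0.36 above random lists in the Ezh1 KO. An indirect effect of the Ezh2 genotype stays open and was not tested.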

How the results depend on the processing

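With no replicates there is no test to pass or fail, and results are compared as values; 4 alternatives were chosen after seeing the data (the highest bin, marked-promoter scaling, the median over exons, and lists matched on WT RNA). Of the log2 ratios of named genes under the alternatives, 4605 stayed on their side of 2-fold, 109 fell under it, 14 passed it and 2 reversed. Of the list values, 198 stayed outside the random range, 23 came within it and 2 reversed. Among counts and direct values, 158 lay within 1.5-fold or the interval of those reported and 171 did not; the latter are printed here. The cause was not tested, except that a lower threshold or minimum counts more features by construction. The highest bin, with a pseudocount large beside its values, counts fewer windows by construction. The H3K27me3 counts of the single KOs rest on 2 to 4 windows in each direction. One promoter per gene was not run because the files hold a single window per symbol, and counting intervals for RNA and the median RNA ratio at 8 times background could not be had.

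Enrichment of marked promoters relative to WT in the Ezh1 KO, Ezh2 KO and double KO was 1.24, 0.810 and 1.00 with windows marked at 2 times background, 1.22, 0.989 and 1.07 at 8 times, 1.28, 0.829 and 1.06 with windows marked in the Ezh1 KO, 1.39, 0.921 and 1.24 with the Hox and developmental lists, 1.25, 0.822 and 1.01 with housekeeping and ribosomal genes as background, and 1.20, 0.884 and 1.05 with means. It stayed above 1 in the Ezh1 KO and below 1 in the Ezh2 KO under all 6. The Hox and developmental windows themselves were not lower in the Ezh2 KO, with medians of 54.9 in WT and 55.3. Their value under 1 came from background medians of 10.1 in WT and 11.1 in the Ezh2 KO. By WT level, median log2 ratios in the Ezh2 KO were -0.13 at 4 to 6 times background, -0.06 at 6 to 8 times and 0.06 at 8 times or more (24 windows).

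In windows of H3K27me3, higher and lower counts follow in that order, against WT unless said. Background scaling gave 1 and 12 in the Ezh2 KO. Median-of-ratios scaling gave 0 and 4 in the Ezh1 KO, 3 and 22 in the double KO against the Ezh1 KO, and 1 and 3 in the double KO against the Ezh2 KO. TMM scaling gave 0 and 4 in the Ezh1 KO, 3 and 23 in the double KO against the Ezh1 KO, and 1 and 3 in the double KO against the Ezh2 KO. A pseudocount of 0.1 gave 6 and 8 in the Ezh1 KO, 7 and 6 in the Ezh2 KO, 13 and 40 in the double KO, 12 and 45 in the double KO against the Ezh1 KO, and 4 and 7 in the double KO against the Ezh2 KO. A pseudocount of 10 gave 0 and 1 in the Ezh1 KO, 1 and 0 in the Ezh2 KO, 1 and 3 in the double KO, 1 and 3 in the double KO against the Ezh1 KO, and 0 and 1 in the double KO against the Ezh2 KO. A 1.5-fold threshold gave 347 and 46 in the Ezh1 KO, 109 and 143 in the Ezh2 KO, 205 and 266 in the double KO, 67 and 392 in the double KO against the Ezh1 KO, and 96 and 52 in the double KO against the Ezh2 KO. A 4-fold threshold gave 0 and 1 in the Ezh1 KO, 1 and 0 in the Ezh2 KO, 1 and 1 in the double KO, 1 and 0 in the double KO against the Ezh1 KO, and 0 and 1 in the double KO against the Ezh2 KO. The highest bin of the window gave 1 and 1 in the Ezh1 KO, 1 and 0 in the Ezh2 KO, 1 and 2 in the double KO, 1 and 0 in the double KO against the Ezh1 KO, and 0 and 1 in the double KO against the Ezh2 KO. Marked-promoter scaling gave 0 and 7 in the Ezh1 KO, 6 and 2 in the Ezh2 KO, 3 and 50 in the double KO, 5 and 9 in the double KO against the Ezh1 KO, and 1 and 10 in the double KO against the Ezh2 KO.

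In RNA, TMM scaling gave 13 and 13 in the Ezh1 KO. Median-of-ratios scaling gave 13 and 14 in the Ezh1 KO and 28 and 16 in the double KO against the Ezh2 KO. With a pseudocount of 0.01, there were 65 and 16 in the double KO. With a pseudocount of 1, there were 8 and 3 in the Ezh1 KO, 27 and 9 in the Ezh2 KO, 22 and 4 in the double KO, 3 and 6 in the double KO against the Ezh1 KO, and 2 and 8 in the double KO against the Ezh2 KO. A minimum of 5 gave 2 and 4 in the Ezh1 KO, 19 and 8 in the Ezh2 KO, 15 and 2 in the double KO, 7 and 1 in the double KO against the Ezh1 KO, and 2 and 5 in the double KO against the Ezh2 KO. Without a minimum, there were 34 and 35 in the Ezh1 KO, 140 and 55 in the Ezh2 KO, 126 and 30 in the double KO, 88 and 27 in the double KO against the Ezh1 KO, and 45 and 91 in the double KO against the Ezh2 KO. A 1.5-fold threshold gave 31 and 142 in the Ezh1 KO, 181 and 150 in the Ezh2 KO, 141 and 124 in the double KO, 132 and 30 in the double KO against the Ezh1 KO, and 71 and 90 in the double KO against the Ezh2 KO. A 4-fold threshold gave 4 and 0 in the Ezh1 KO, 16 and 1 in the Ezh2 KO, 5 and 2 in the double KO, 1 and 4 in the double KO against the Ezh1 KO, and 1 and 8 in the double KO against the Ezh2 KO. The median over exons gave 59 and 37 in the Ezh2 KO and 30 and 20 in the double KO against the Ezh2 KO.

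Lists outside the random range numbered 6 for H3K27me3 in the Ezh1 KO with lists matched on WT RNA. With means they numbered 9 for H3K27me3 in the Ezh2 KO, 10 for H3K27me3 in the double KO against the Ezh1 KO and 4 for RNA in that comparison, and without a minimum 9 for RNA in the double KO and 12 against the Ezh2 KO. The CD8 T and NK cell list in RNA of the double KO against the Ezh1 KO reversed to -0.0035 without a minimum, and the stress list there to -0.0142 with means. Ccdc107 RNA in the double KO reversed to -0.21 and Ifi204 to 0.15 with the median over exons. Marked promoters at least 2-fold lower numbered 2 in the Ezh1 KO, 1 in the Ezh2 KO and 24 in the double KO at 2 times background, 1 in the double KO at 8 times, 0 in the Ezh1 KO with windows marked there, and 2 in the Ezh2 KO with background scaling.

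Shared windows at 1.5-fold, higher and lower, were 8 and 2 for the single KOs, 52 and 6 for the Ezh1 KO and double KO, and 25 and 77 for the Ezh2 KO and double KO. At 4-fold they were 0 and 0, 0 and 1, and 1 and 0. Shared RNA at 1.5-fold was 23 and 67, 19 and 48, and 83 and 57, in the same order. At 4-fold it was 4 and 0, 0 and 0, and 3 and 0, and with a minimum of 5 it was 1 and 4, 2 and 1, and 10 and 1.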

Other observations

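All tests in this part were chosen after the data were seen. In the double KO 266 windows had at least 1.5-fold less H3K27me3 than in WT. By WT level they were 9 of the 5074 windows under background, 69 of 7112 at 1 to 2 times background, 106 of 2321 at 2 to 3 times, 53 of 1238 at 3 to 4 times, 27 of 1776 at 4 to 6 times, 1 of 431 at 6 to 8 times and 1 of 24 at 8 times or more. Windows at least 1.5-fold higher numbered 64, 84, 44, 5, 8, 0 and 0 in the same order. WT values set the bins and also enter the ratio, so windows high by chance in WT shift toward lower ratios in higher bins. In the bin of 2 to 3 times background the median log2 ratio over WT was 0.18 in the Ezh1 KO, -0.15 in the Ezh2 KO and -0.01 in the double KO, and at 4 to 6 times 0.30, -0.13 and 0.12. At the 25 windows at least 2-fold lower in the double KO, the median log2 ratio was -0.61 in the Ezh2 KO, lower than WT in 24 of 25, and -0.00 in the Ezh1 KO, lower in 13 of 25. Both ratios share the WT library that helped to choose these windows, so chance high WT values would lower them by construction. Matched on WT RNA instead of H3K27me3, the naive T cell list was 0.31 above random lists in the double KO and 0.18 in the Ezh2 KO.

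Several genes known from other tissues or cell types had RNA that differed between libraries, in different patterns. Glycam1, an adhesion ligand of lymph node venules, was at 0.244 in WT, 0.432 in the Ezh1 KO, 0.431 in the Ezh2 KO and 1.47 in the double KO. Psp, a salivary secretory protein gene, was listed at 0 in WT and was at 0.825, 0.577 and 1.55 in the mutants, and the macrophage lysozyme gene Lyz2 was at 0.275, 0.561, 0.576 and 1.19. The uncertain pancreatic amylase genes, Amy2a3 for example, were highest in the Ezh2 KO, with 0.119, 1.89, 3.42 and 0.253, as was Igj with 0.260, 0.423, 1.79 and 0.419. The B cell genes Ms4a1 and Cd79a were at 0.189 and 0.359 in WT, 0.252 and 0.499 in the Ezh1 KO, 0.321 and 0.755 in the Ezh2 KO, and 0.926 and 1.12 in the double KO, against a Cd4 RNA of 16.6, 13.6, 15.7 and 16.3. The tissue is given as purified CD4 T cells. In WT 4 of the 24 measured B cell list genes reached an RNA of 1, and 1 of the 27 listed is also in another list. In the B cell list 23 of 24 measured genes were higher in the double KO than in WT. Zbtb16, the transcription factor of innate-like T cells, was chosen after its values were seen; it was at 0.0470 in WT, 0.0915 in the Ezh1 KO, 0.619 in the Ezh2 KO and 0.0430 in the double KO.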
